A study of Staphylococcus aureus with 2 samples.

How the data were processed

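RNA of MT02-treated and untreated S. aureus HG001 was compared on 2 two-colour Agilent arrays with probes of 25 to 60 bases. Per the file headers, the authors' scans were quantified with Agilent Feature Extraction 9.5.3.1. The deposited scanner files give, per spot and channel, an intensity as the mean signal with the median of its local background, and Agilent's own log10 ratio of cyanine 5 over cyanine 3 after background subtraction and dye normalization. The median spot intensity per the deposited files was 636 and 667 in the untreated and treated channel of array 1, and 571 and 538 on array 2. Negative control spots had medians of 46.5 and 74.7 on array 1, and 53.9 and 80.2 on array 2. A deposited value table of the series holds 6608 rows of log10 ratios with a median of 0 on each array. Its row numbers match no probe column, but all 6608 rows were found in order among Agilent's log10 ratios on both arrays at 3 significant digits. Scale and direction are therefore those of that column and no centring was added; the rows stay unnamed. It has 0 columns of other samples.

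Gene names were taken from the annotation string of the scanner files, which holds locus tags of several strains; the meaning of its asterisks is not given in the sources used here. Of 10426 probes, 4093 carry a SAOUHSC tag, of the strain from which HG001 derives (2654 genes), 2515 carry only another gene name (2257 names) and 3818 carry none. The RefSeq gene table of assembly ASM1342v1 held 2576 of the 2654 tags and a symbol for 217. The files name no genome build, so no coordinates are given, and the table served only for symbols and for which genes are neighbours. It gives no descriptions, so genes without a symbol are named by tag alone. Members of gene lists were matched by symbol or synonym. Members known by tag alone are therefore missing from every list, and a measured member is one that could be matched.

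Spots were read in R 4.3.3 with limma 3.58.1. Background was corrected with normexp and an offset of 50, and ratios were normalized within each array by loess, with weight 0 for control spots and spots marked as non-uniform or population outliers. Those spots were then left out (134 and 51 outlier spots on arrays 1 and 2), and saturated spots were kept. A probe was kept if well above background in at least 1 channel on both arrays, which held for 6903 probes, 6811 of them free of outlier marks. Probes of a gene were averaged. The 5471 features, counting each probe without a gene name as its own feature, were fitted with lmFit and eBayes against a log2 ratio of 0 (1 residual degree of freedom, prior 3.72), with Benjamini-Hochberg adjustment over all features. Log2 ratios are treated over untreated; errors are the SD between the arrays. Of 216 genes past the test with 2 or more probes, all 216 had every probe in one direction.

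Spots were simulated for 5471 features with the arrays' own dye curves and a spread drawn from the fitted prior. The test recovered 98.5% of 66 genes changed 4-fold, 59.7% of 67 at 2-fold and 2.99% of 67 at 1.5-fold. Of its 113 calls, 5.31% were unchanged genes. In the data a larger share passed, 539 of 2364 genes with a SAOUHSC tag, so the adjusted cutoff was looser there. The recovery of small changes in the simulation therefore does not describe the test on the data. Camera on simulated lists of 20 genes called 10 of 10 lists shifted by 1 on the log2 scale and 0 of 40 unchanged ones. The tested lists hold 3 to 48 genes. With a shift of 1 added to random lists of measured ratios, 1 list among 11, camera called 45.5% of 200 lists of 3 genes, 87% of 5 genes and 100% of 14 genes. Genes of all these lists were drawn at random. The rates therefore do not describe lists that hold neighbouring genes, such as urease.

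Gene lists, tests and alternatives were fixed before the data were examined, except 8 lists written once the gene names were known, the alternatives named as added, camera on shifted lists of measured ratios, and the tests said elsewhere to be chosen after the result was seen. Lists were tested with camera at a preset correlation of 0.01 and with fry, with adjustment over the lists. Camera was run again with an estimated correlation, which rests on 1 residual degree of freedom. The estimates reached 1 for the SOS list and -0.333 for urease, and 0 of 11 lists had an unadjusted p under 0.05. That form can hardly pass with 2 arrays, so its p-values weigh neither for nor against a list. Camera on simulated and shifted lists used the preset correlation only. Fry's p-value asks whether a list moves one way on balance and compares it with no other gene. Named genes are the 10 highest and 10 lowest with a symbol past an adjusted p of 0.05 with one sign on both arrays, recA and lexA in any case, and up to 2 highest and 2 lowest members of each list. A further part of the rule, up to 5 genes per direction with a description but no symbol, named none for want of descriptions. The alternatives covered background, normalization, the dim-probe filter, probe averaging, the variance model, the pairing of channels, the value table and each array alone. Slide and scan gave no batch contrast, as both arrays share them. Other splits of the samples were not counted, since there are only 2 arrays of 1 kind.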

Results

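Gene expression was measured in Staphylococcus aureus HG001, a laboratory strain, with and without the antimicrobial compound MT02. Per the labels, cultures in Mueller-Hinton broth at an OD600 (optical density) between 0.6 and 0.8 were exposed for 60 min or left untreated. RNA of treated cells carried cyanine 5 and RNA of untreated cells carried cyanine 3, and one of each was hybridised together on each of 2 arrays. Each array therefore gives 1 ratio of treated over untreated cells per probe, and every mean below is over n = 2 arrays. Both arrays lay on 1 slide and were read in 1 scan. Of 10426 probes that are not controls, 6996 and 7236 were well above background in the untreated channel of arrays 1 and 2, and 6999 and 7508 in the treated channel. The number of arrays limits the precision of all values.

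The comparison asks which transcripts differ after an hour with MT02, a compound whose mode of action the series set out to study. Among genes with a symbol, nrdI, recA, nrdF and uvrA had the highest ratios, and mraW, mraY and murD the lowest. The recombinase gene recA rose 4.66-fold (log2 ratio 2.22 ± 0.14, SD, n = 2, limma adjusted p = 0.00333). The ribonucleotide reductase genes nrdI and nrdF rose 5.63-fold (2.49 ± 0.70) and 4.64-fold (2.21 ± 0.51). The excision repair gene uvrA rose 3.50-fold (1.81 ± 0.21). The lowest ratio of a gene with a symbol was that of mraW, a methyltransferase gene, which was 4.18-fold higher in untreated cells (log2 ratio -2.06 ± 0.05, adjusted p = 0.00333). Of these genes, recA, nrdI and mraW were each read by 1 kept probe, and nrdF and uvrA by 2.

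Over all 2364 tested genes with a SAOUHSC locus tag, the tags of the strain from which HG001 derives, 539 passed an adjusted p of 0.05 in limma, with 298 higher and 241 lower in treated cells. A change of at least 2-fold on both arrays was seen in 168 genes, 128 higher and 40 lower, and all 168 also passed the test. In 18 of them one channel was not well above background on either array and in 7 more on 1 array only, and with the 18 at their bounds the count was 163. The log2 ratios of the arrays had a Pearson correlation of 0.864 and a Spearman correlation of 0.781 across these genes, which are not independent replicates. The ratio had one sign on both arrays in 79.7% of them. With median centring in place of loess the split changed to 307 higher and 398 lower, a share of 43.5% higher against 55.3%. Names other than a SAOUHSC tag, that is tags of other strains or plain gene names, added 1397 tested features. Of these 340 passed, 186 higher and 154 lower. Whether they are genes apart from the 2364 was not tested.

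**Figure D1:**
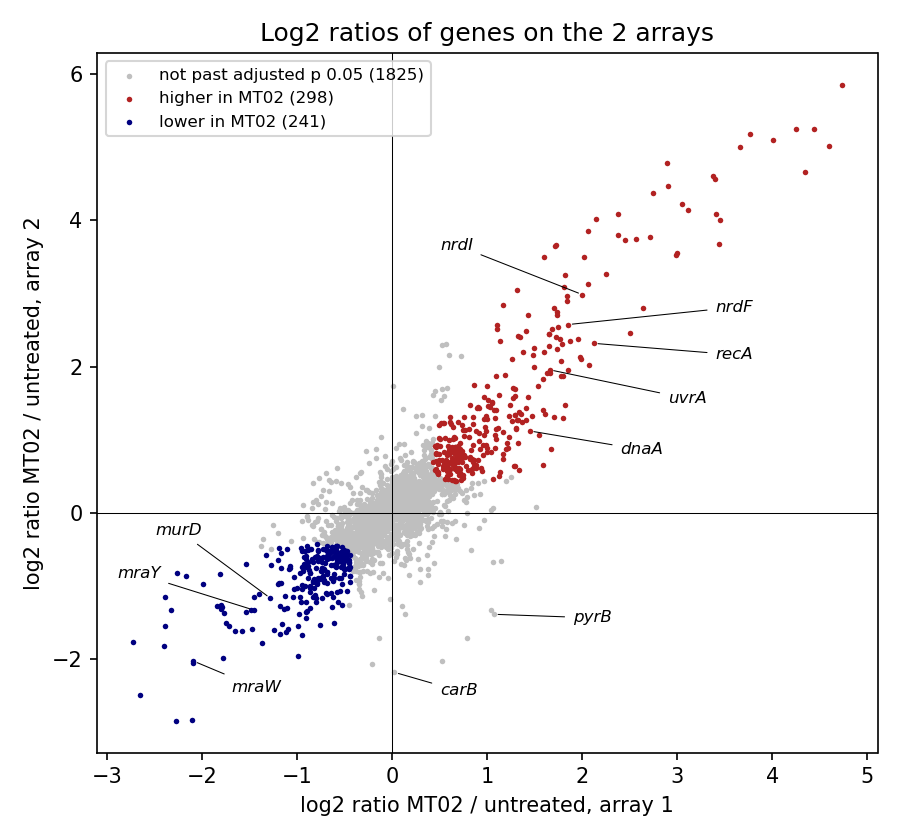
Log2 ratio of MT02-treated over untreated cells on array 1 (x axis) and array 2 (y axis), 1 point per gene with a SAOUHSC locus tag; red and blue points are the 298 higher and 241 lower genes past an adjusted p of 0.05. Points of recA, nrdI, nrdF and uvrA lie high on both axes, while pyrB and carB lie apart from the diagonal.

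Of the SOS response list, the genes under the repressor LexA, 3 members were measured, and 2 rose. These were recA and uvrA, while recX, a regulator of RecA, had a log2 ratio of -0.38 ± 0.04 with adjusted p = 0.0869. Adjusted over the list alone, 2 were higher and 1 lower. The gene of LexA itself has no symbol in the reference table and is not reported. Of 5 genes of ribonucleotide reduction and thymidylate supply matched by symbol and measured, 2 rose (nrdI and nrdF), also when adjusted over the list alone. nrdI and nrdF lie in a row of 3 measured neighbours, all at least 2-fold higher on both arrays and past the test. The gene between them was not matched by symbol, so the counts and tests of the list leave it out. The kinase genes ndk and tmk had log2 ratios of 0.09 ± 0.25 and 0.07 ± 0.01 and did not pass.

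Of 19 genes written in the DNA replication list, 2 were matched by symbol and measured. The initiator gene dnaA rose 2.43-fold (1.28 ± 0.23, adjusted p = 0.00871), and polC, a DNA polymerase gene, had -0.48 ± 0.01 (adjusted p = 0.0533); adjusted over the list alone, 1 was higher and 1 lower. Of 7 repair genes outside the SOS list, 1 rose, recF, by 2.48-fold (1.31 ± 0.03). The others did not pass, and ranged from recR at 0.40 ± 0.21 to recU, a Holliday junction resolvase gene, at -0.66 ± 0.38, with the mismatch repair gene mutL at -0.46 ± 0.15. Adjusted over the list alone, 1 was higher and 2 lower. dnaA, recF, rplI, panB, hisG and hisH lie in the tenth of the gene order nearest the replication origin, where the median log2 ratio of 226 genes was 0.57 against -0.05 in 2027 genes elsewhere, with 56 genes in rows of 5 or more changed neighbours left out.

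**Figure D2:**
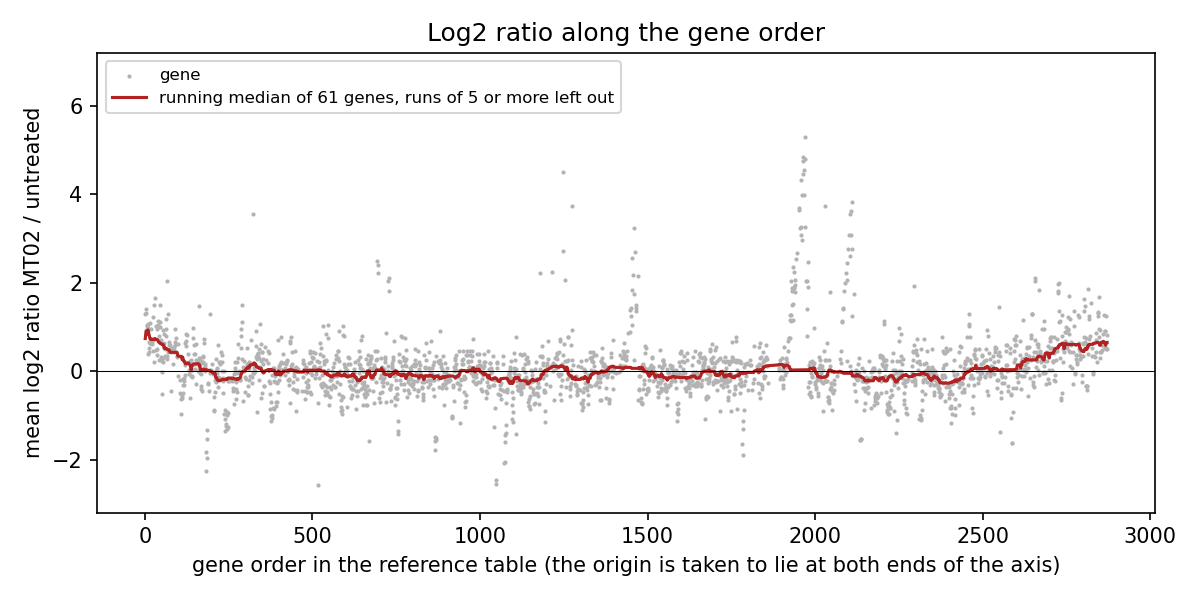
Mean log2 ratio of MT02-treated over untreated cells on 2 arrays (y axis) by gene order in the reference table (x axis); grey points are genes and the red line is the running median of 61 genes without rows of 5 or more changed neighbours. The line rises towards both ends of the axis, where the origin is taken to lie, and single rows of genes stand above 3.

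The other genes with the highest ratios were gpmA, for a phosphoglycerate mutase (2.72-fold, log2 ratio 1.45 ± 0.22), rplI, for a ribosomal protein (1.08 ± 0.32), panB, of pantothenate synthesis (0.89 ± 0.48), and pdf1 (0.56 ± 0.11). Adjusted p values of these 4 genes lay between 0.00691 and 0.0412. The call of panB, whose log2 ratio was 0.55 on array 1 and 1.23 on array 2, was lost without background subtraction (adjusted p = 0.0544), without the filter on dim probes (0.0570) and with a robust variance model (0.0531). That of pdf1 was lost with Agilent's ratios (0.0613) and with median centring (0.0698).

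Below mraW, the wall precursor genes mraY and murD fell, with log2 ratios of -1.40 ± 0.09 and -1.23 ± 0.08. mraW, mraY, murD and 3 others form a row of 6 measured neighbours, all at least 2-fold lower on both arrays. glmM, of amino sugar synthesis for the wall, had -0.83 ± 0.10 (adjusted p = 0.0166). hslU, a protease subunit gene, was 1.80-fold higher in untreated cells (-0.85 ± 0.03). glpK, for glycerol kinase, had -0.90 ± 0.46, upp, for uracil phosphoribosyltransferase, -0.83 ± 0.12, and glyA, for serine hydroxymethyltransferase, -0.83 ± 0.09, and all 3 passed. glpK, with -0.58 on array 1 and -1.23 on array 2, did not pass without background subtraction (adjusted p = 0.0501) or without the filter on dim probes (0.0517).

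**Figure D3:**
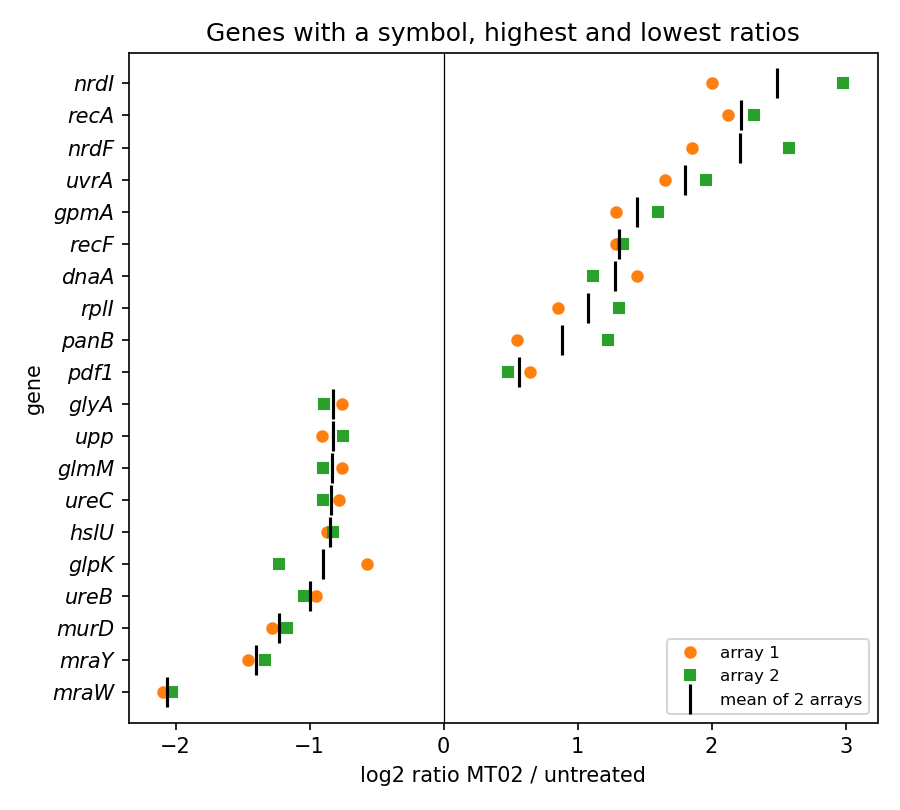
Log2 ratio of MT02-treated over untreated cells (x axis) for the 10 highest and 10 lowest genes with a symbol past an adjusted p of 0.05 (y axis); circles and squares are arrays 1 and 2, bars the mean of 2 arrays. The means run from 2.49 for nrdI to -2.06 for mraW, and ureB is drawn at its measured ratio although its treated channel was not well above background.

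Of 4 measured urease genes, 3 fell, also when adjusted over the list alone. ureA had a log2 ratio of -0.63 ± 0.01 and ureC of -0.84 ± 0.09, with its treated channel well above background on 1 of 2 arrays (-1.31 with Agilent's ratios). The treated channel of ureB was not well above background on either array, so only a bound holds, at least 1.36-fold higher in untreated cells (adjusted p = 0.0103). Such bounds set the brighter channel against the lowest signal of probes above background, and remain open to dye bias. ureE had -0.16 ± 0.23 and did not pass. The list's median log2 ratio was -0.74 as measured and -0.54 with ureB at its bound. As measured it lay at percentile 0.32 among 10000 random lists matched on signal. Limma's camera gave an adjusted p = 0.0938 with the preset correlation. The 4 genes are direct neighbours in the gene order. The random lists drew genes one by one and the preset correlation is small, so neither allows for neighbours that move together. The percentile and this adjusted p can therefore overstate how far the list stands out. With an estimated correlation camera gave an adjusted p = 0.743, but that form can hardly pass with 2 arrays and decides nothing.

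Of 48 measured ribosomal protein genes, 1 rose (rplI) and 2 fell, rpsA (-0.72 ± 0.24) and rplB, the latter named after its value was seen; 45 did not pass, among them rplQ (0.51 ± 0.62) and rplW (-0.58 ± 0.25). None passed when adjusted over the list alone. The median log2 ratio of the list was -0.12. Several of the 45 differed in sign between the arrays, in both directions. Named after their values were seen, rpsE had -0.83 on array 1 and 0.41 on array 2, and rplT had 0.29 and -0.95. Of 14 aminoacyl-tRNA synthetase genes, 1 rose, asnC (0.52 ± 0.06, adjusted p = 0.0466; between 0.0502 and 0.0694 under 5 alternatives, and so not past the test), and none passed when adjusted over the list alone; argS had 0.37 ± 0.02, aspS -0.39 ± 0.09 and leuS -0.45 ± 0.08. Of 5 glycolysis genes matched by symbol, 2 fell, tpiA (-0.76 ± 0.20) and pgk (-0.60 ± 0.20), also when adjusted over the list alone. pfk had 0.20 ± 0.14 and eno -0.19 ± 0.26. The list does not hold gpmA, for a phosphoglycerate mutase, which rose 2.72-fold. pgk did not pass without background subtraction (adjusted p = 0.0519) or with an offset of 0 (0.0503).

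No gene passed among 6 of pyrimidine synthesis, 5 of the TCA cycle, 4 of protein quality control and 3 of histidine and branched-chain amino acid synthesis, nor when adjusted over each list alone. The chaperone genes groEL, groES and dnaK had log2 ratios of -0.11 ± 0.04, 0.16 ± 0.14 and -0.12 ± 0.04, and the protease gene clpP 0.32 ± 0.31. sucA and sucC had -0.53 ± 0.42 and -0.20 ± 0.23, and sdhB 0.35 ± 0.05. fumC had 0.24 ± 0.15, with 1 of its 2 probes saturated in the treated channel on 1 array; the other probe had -0.09 ± 0.12. hisG and hisH had 0.33 ± 0.04 and 0.35 ± 0.23, and leuD -0.16 ± 0.23. The arrays differed in several pyrimidine genes. carB had 0.02 on array 1 and -2.18 on array 2, and pyrB had 1.07 and -1.39. pyrE had -0.93 ± 1.11 and pyrG 0.03 ± 0.01.

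Lists with fewer than 3 measured members were not tested. guaA and purH of purine synthesis had log2 ratios of 0.44 ± 0.12 and -0.55 ± 0.19; adjusted over the list alone, 1 was higher and 1 lower. acpP and fabZ of fatty acid synthesis had 0.37 ± 0.10 and 0.04 ± 0.12, atpC of ATP synthase -0.48 ± 0.60, tpx of peroxide defence 0.32 ± 0.22, and SAOUHSC_00608, in the fermentation list, -0.04 ± 0.13. hld, in both virulence lists, was saturated in both channels on both arrays and has no ratio. The lists on SigB stress, wall stress, envelope defence, autolysis, iron uptake, efflux, capsule, prophages and transposases had 0 measured members that could be matched by symbol.

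Over the 11 lists tested, limma's camera called 0 at an adjusted p of 0.05, 2 at an unadjusted p under 0.05, and 0 with an estimated correlation. The self-contained test fry also called 0, and 2 at an unadjusted p under 0.05; with an offset of 0 it called 1, urease (adjusted p = 0.026), where camera gave adjusted p = 0.739 with an estimated correlation. The highest medians, over members matched by symbol alone, were those of the SOS list and the ribonucleotide list. The SOS list had 1.81 (percentile 99.8, camera adjusted p = 0.27). The ribonucleotide list had 0.42 (percentile 95.5, camera adjusted p = 0.163), with a median of 0.26 on array 1 and 0.69 on array 2. Its nrdI and nrdF lie in one row of neighbours, for which the random lists do not allow. Camera with an estimated correlation gave adjusted p = 0.743 for both. That form can hardly pass with 2 arrays, so its values in this paragraph decide nothing.

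Among genes with a SAOUHSC tag, the highest ratios belonged to genes without a symbol, named here by locus tag and chosen after their values were seen. SAOUHSC_02080 had a log2 ratio of 5.29 ± 0.79 and SAOUHSC_02073 of 4.85 ± 0.58. Both lie in a row of 29 measured neighbours, SAOUHSC_02043 to SAOUHSC_02087, with measured ratios at least 2-fold higher on both arrays and a median of 3.09. The row spans 43 genes of the reference order, since genes without a tested value are passed over. The untreated channel of 2 of the 29 genes was not well above background. With both at their bounds 28 of the 29 were at least 2-fold higher, SAOUHSC_02050 being at least 1.52-fold higher, and the median was 2.96. Outside that row, SAOUHSC_01334 was at least 16.7-fold higher in treated cells, its untreated channel being not well above background (adjusted p = 0.00301). The lowest were SAOUHSC_00545 at -2.57 ± 0.12, SAOUHSC_01114 at -2.56 ± 0.40 and SAOUHSC_01115 at -2.47 ± 0.51. Without the genes in rows of 3 or more such neighbours, 68 genes were at least 2-fold changed on both arrays in place of 168.

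Both arrays had the same dye orientation, so dye and treatment cannot be separated for any gene, and the labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these arrays. When the channels were fitted as 4 separate samples with no replicate block, 12 genes passed in place of 539, and of 25 genes named by symbol that passed with pairing 2 passed, recA and mraW (adjusted p = 0.0495 for both).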

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

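Probes without a gene name were left out of the comparisons above, and 246 of 1710 such probes passed an adjusted p of 0.05 in limma, a signal in data not otherwise reported. Of these, 136 were higher and 110 lower in treated cells, and 44 and 17 were at least 2-fold higher and lower on both arrays (41 and 15 with dim channels at their bounds). Their measured mean log2 ratios ran from -2.05 to 4.36. The annotation string places 979 of the 1710 probes between genes of the strain with SAOUHSC tags, and 137 of these passed.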

How the results depend on the processing

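The value table, Agilent's ratios and the leave-one-array-out values were planned; the alternatives that leave out genes, count every gene name, drop rows at 0 or set genes at their bounds were chosen after seeing the data. Across 63 genes named by rule and the gene lists no call changed direction. Of 25 such genes past the test, 5 lost their call under at least 1 of 10 alternatives that keep the pairing of channels: panB, pdf1, glpK, asnC and pgk (adjusted p between 0.0501 and 0.0698). Without pairing 23 lost it. Of those not past the test, 8 gained a call: polC under 4 alternatives, purH under 3, rplW under 2, and recX, mutL, recU, aspS and leuS with median centring alone. The count of genes past an adjusted p of 0.05 stayed between 467 and 705 over the planned changes of background, normalization, filter, averaging and variance model, and at 534 for genes with at least 1 probe past the test. Aquantile changes no ratio, by construction. Beyond 1.5 times, median centring gave 398 lower genes in place of 241, and the fit with no replicate block, that is without the pairing of channels on an array, gave 12 genes, 10 higher and 2 lower, all 12 among the 539. The value table's rows gave 0 calls with limma, 0 higher and 0 lower (1943 at an unadjusted p under 0.05), because 444 rows at exactly 0 on both arrays pull the prior degrees of freedom to 0.732; without those rows it gave 886 calls, 469 higher and 417 lower. These rows are probes of any kind, not genes: 471 were at least 2-fold on both arrays, 307 higher and 164 lower, with or without the rows at 0. Counting every gene name gave 879 named features past the test (484 higher, 395 lower) and 282 at least 2-fold (217 higher, 65 lower). Leaving out the tenth of genes nearest the origin gave 196 higher genes in place of 298. Leaving out rows of 3 or more neighbours gave 68 genes at least 2-fold, 45 higher and 23 lower. Agilent's ratios gave 67 genes at least 2-fold lower in place of 40, and 1 list past camera in place of 0, urease (adjusted p = 0.0447, and adjusted p = 0.885 with an estimated correlation; its range was 0.0447 to 0.175 over the alternatives that keep 3 or more of its genes). Fry called urease with an offset of 0 (adjusted p = 0.026, adjusted p = 0.0635 in camera, and adjusted p = 0.739 with an estimated correlation). Camera with an estimated correlation can hardly pass with 2 arrays, so its values decide nothing. Bounds for dim channels gave 163 genes at least 2-fold, 124 higher and 39 lower. A 1.5-fold rule gave 392 genes, 241 higher and 151 lower. On a single array, which allows no test, the genes at least 2-fold were 218 to 276, with 153 to 187 higher and 65 to 89 lower. Unless stated, the cause was not tested. List shifts and named genes were not run on the value table, whose rows are unnamed, and single arrays gave no count past a test. Genes near background have ratios drawn towards 0 by the offset.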

Other observations

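In this part the tests of genes called on 1 drawn probe, of probes between genes, of spot position and probe GC content for the position pattern, of shuffled gene order and of strain tags were chosen after the result was seen, as were the bounds for rows of genes. For the change from origin to terminus, least squares with block resampling was chosen after a robust fit had been seen, whose changes ran from -0.54 to -0.30 over arms and arrays. Lists written once the gene names were known, but before any ratio was computed by gene, add the following values, with members named after their values were seen. Of 8 measured peptidoglycan precursor genes, 3 fell (mraY, murD and glmM), 5 did not pass, and murG had a log2 ratio of 0.43 ± 0.20. Of 11 translation factor genes, 2 fell, infB (-0.71 ± 0.06), for an initiation factor, and smpB (-0.63 ± 0.17), of ribosome rescue. Of 10 ribosome assembly genes, 1 fell, mraW, and of 7 genes of RNA polymerase and transcription factors, 1 fell, nusA (-0.75 ± 0.04). No gene passed among 11 of tRNA modification, 7 of protein export, 4 of haem and 2 of tryptophan and arginine synthesis. The 7 of these lists with 3 or more members gave 0 camera calls at an adjusted p of 0.05 and 2 at an unadjusted p under 0.05. Fry called 0 of the 7 for a shift one way (3 at an unadjusted p under 0.05) and 4 in its mixed form, which asks for change in either direction: peptidoglycan precursors, ribosome assembly and tRNA modification (adjusted p = 0.0264 each) and RNA polymerase and transcription factors (adjusted p = 0.0409). Camera with an estimated correlation called 0 of the 7, with adjusted p = 0.711 for tRNA modification and adjusted p = 0.694 for the other 3 of these. That form of camera can hardly pass with 2 arrays and decides nothing. In the mixed form fry called 0 of the 11 lists fixed earlier, with 4 at an unadjusted p under 0.05. The mixed form compares a list with no other gene, and 22.8% of all tested genes with a SAOUHSC tag passed the test. A call in it therefore does not set a list apart from other genes. gidB (0.50 ± 0.23) and trmE (0.49 ± 0.12), the highest of the tRNA modification list, lie in the tenth of the gene order nearest the origin.

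The 4 pyrimidine genes carB, pyrB, pyrC and pyrE differed between the arrays, each with a higher ratio on array 1 than on array 2. pyrC had 0.78 and -1.72, and pyrE -0.14 and -1.71. None passed the test. Differences between the arrays were not confined to these genes, as with the ribosomal protein genes rpsE and rplT above.

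Genes called between treated and untreated cells share 1 dye orientation. In 100% of 216 called genes with 2 or more probes every probe had the direction of the gene, but calling on the mean of the probes favours this, and probes dealt at random among genes gave a median of 75.2% (at most 83.3% in 200 shuffles). Probe-specific dye bias is argued against, for genes with 2 or more probes, by genes called on 1 drawn probe: the other probes had its direction in 98.5% of 201 genes (95% exact interval 95.7 to 99.7), and in 155 of 158 whose probes share no 15 bases. Genes read by 1 kept probe lie outside this check, and for them probe-specific dye bias stays open. Among them are recA, nrdI, mraW, SAOUHSC_02080, SAOUHSC_02073 and SAOUHSC_01334. Probe GC content had a Spearman rho of 0.0427 with the log2 ratio across probes, and 608 genes passed after a GC trend was removed. A dye effect that acts on a whole transcript stays open, since no swap was made, and so does treatment, the contrast of the design.

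The log2 ratio depended on position along the chromosome. In the tenth of the gene order nearest the origin, taken to lie beside dnaA, 102 of 226 genes were higher past the test and 7 lower, and the median exceeded that of the other genes by 0.51 on array 1 and 0.67 on array 2, without genes in rows of 5 or more changed neighbours. Spot position on the array and probe GC content are argued against, as 0.978 and 1.00 of the difference remained after each trend was removed. A candidate explanation is gene dosage, more copies near the origin in treated cells: probes between genes showed the excess too, by at least 0.481 on both arrays. The change from origin to terminus was smallest in size at -0.273, with intervals that include 0 on one arm of the chromosome and not on the other, and without the genes nearest the origin it was 0.03 and 0.05 on the first arm and -0.30 and -0.29 on the second; no DNA was measured, so dosage and regulation of these genes stay open.

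Rows of neighbouring genes, counted over measured genes alone, rose together, and others fell together. Of 125 genes at least 2-fold higher on both arrays and placed in the gene order, 83 lay in 15 rows of 3 or more, the longest of 29 genes; with dim channels at their bounds 80 of 121 lay in 16 rows, the longest of 22 genes. In 10000 shuffles of the gene order the longest row had 5 genes, measured or at bounds (permutation p = 1e-04, the smallest these shuffles can give), which argues against chance adjacency, though genes of one operon are adjacent in any case; of 38 genes at least 2-fold lower, 17 lay in 4 rows (14 of 37 in 3 at bounds), the longest of 6 genes against at most 4 in shuffles, with the same p. A hypothesis is that the higher rows of 5 or more genes belong to mobile genetic elements. Prophages, which the parent strain of HG001 is known to carry, are an example. Probes of the 50 genes in these higher rows had tags of a median of 1 of 7 other strains. The median was 6.25 for other genes, among them the lower row of 6, a difference of -5.25. Whether the genes of the higher rows are phage genes stays open, as the reference table gives no descriptions. More copies of an excised element and more transcription per copy were not tested.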
